A study of Homo sapiens with 8 samples.

How the data were processed

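Ribosome footprints of 293T cells were measured in 8 libraries, 2 in each of 4 groups. Per the labels' protocols, cells were lysed in a polysome buffer with cycloheximide, which holds ribosomes on mRNA, and libraries were made with a modified mammalian ribosome profiling kit. Per the submitters' processing notes, cutadapt and Bowtie were used with the GRCh38 build. Their versions and roles, the counting tool, the removal of rRNA reads and the treatment of reads that match several genes are not given in the sources used here. The values deposited by the authors are whole-number counts of mapped reads per feature, not normalized, with no header. Each feature pairs a gene with a transcript, and a feature with no read is not listed, so it was taken as 0. The labels do not spell out NBD1, and the reporter row was used as the files name it. Cycloheximide can redistribute ribosomes along a message, which these per-gene counts cannot show.

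The 18037 features were summed to 17179 gene symbols, of which 279 had several features. Total counts were 14806820 and 12060938 in the shRNA control, 14162769 and 14744247 with shNBD1, 19050037 and 19854218 in the inhibitor control, and 15637644 and 11218980 with the inhibitors. Features named ZNF354B and ST8SIA1 took between 5.99% and 11.3% of the counts together, most in inhibitor replicate 2, and genes of the MTRNR2L family between 0.793% and 1.83%. No row lacked a gene name. Of the tested genes, 12760 had a symbol in the RefSeq table given for GRCh38.p14, which supplied the coordinates, and 546 did not. Intervals and errors do not cover the amplification of reads in library preparation.

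Groups were compared with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), libraries scaled by TMM, and a quasi-likelihood model with the 4 groups and no other term fitted over all 8 libraries. With 4 residual degrees of freedom, the spread was shared across arms. The common biological coefficient of variation was 0.0753. P-values were adjusted by Benjamini-Hochberg over 13306 genes, with a threshold of 0.05. The comparisons were shNBD1 against its control, inhibitors against their control, the difference between these effects, and the shRNA control against the inhibitor control. CPM values use the TMM-scaled library sizes. Fold changes are given with the SE implied by the test.

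Lists of genes were fixed before the data were examined: RISC and miRNA processing, deadenylation and decapping, let-7, miR-17 and miR-15/16 targets, HSF1 chaperones, TRiC and prefoldin, ER unfolded protein response, ATF4 targets, cytosolic ribosomal proteins, translation factors, ribosome collision, proteasome, interferon-stimulated genes, p53 targets, mitotic genes, histones, mitochondrially encoded proteins, nuclear oxidative phosphorylation, cholesterol synthesis and markers of other cell types. They were tested with camera on voom values at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The form with an estimated correlation takes its p from 4 residual degrees of freedom, so it has less power even where the correlation is not positive. At the preset correlation 8, 13, 9 and 3 lists passed in the 4 comparisons, with the estimated correlation 0 in each, and fry, which does not compare a list with other genes, passed 5, 7, 4 and 10. A further 4 lists (DUX4 targets, YAP and TAZ targets, SRF and actin targets, immediate early genes) were written after the values had been seen.

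Named genes followed a rule also fixed before the data were examined. For each treatment these were the called genes with both treated libraries on the same side of both controls and a mean of at least 50 counts in the higher group, 12 of smallest p in each direction. Where under 10 were found, up to 5 not past the threshold were added as values. Each list gave up to 4 called members with the largest change, or 2 of smallest p as values. The 6 of smallest p in each direction were taken for the difference and for the controls. Some members of lists with several called genes are given only as counts, and 1 further gene fixed by the rule was not analysed here. CD68 and ACTA2 between the controls were chosen after their values were seen.

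The steps were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 changed genes. These were taken from genes with a mean of at least 50 counts, so recovery at lower counts was not simulated. For shNBD1 against its control (13153 genes), 14% of 1.25-fold, 66% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes were recovered, with 13 unchanged genes among 150 calls. For the inhibitors (13133 genes) the shares were 14%, 68%, 96% and 100%, with 15 unchanged genes among 154 calls. The simulation gave both arms the same dispersion, while the real inhibitor arm varied more, so it overstates the power and understates false calls there. In a test of 21 lists of 25 genes, the list raised by 1.5-fold passed and 0 of 20 unchanged lists did, in both comparisons. Simulated genes were drawn independently, so this cannot show how often lists whose members vary together pass falsely. In the real data the estimated correlation was 0.736 for ribosomal proteins with shNBD1.

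Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, features as deposited, robust shrinkage, only the libraries of a comparison, the replicate number as a block and leaving out each library. Chosen after seeing the data were voom with sample quality weights and a fit without inhibitor control replicate 1 and inhibitor replicate 2. Planned tests of seed sites need transcript sequences and were not run. Groups of 2 libraries are too small to count other splits of the samples.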

Results

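Ribosome profiling sequences the short stretches of mRNA that ribosomes protect from nuclease, so the count of a gene reports the abundance of ribosome footprints on it. The libraries came from 293T cells, a human embryonic kidney line that carries the SV40 large T antigen. They fell into 4 groups of 2 libraries, which form a pair of arms. In the shRNA arm, cells with a non-cleaving short hairpin RNA named shNBD1 were set against a control for shRNA. In the inhibitor arm, cells with miRNA inhibitors were set against a negative control. The design text gives the translation status of cells under both treatments as the question. Total counts per library ranged from 11218980 to 19854218. No matched RNA libraries were used here, so a change in footprints can reflect mRNA level, translation or both, and the counts hold no positions along transcripts. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All 4 replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 1.42 in the shRNA control, 2.77 with shNBD1, 14.4 in the inhibitor control and 21.1 with the inhibitors. This measure uses raw counts, so abundant features weigh most in it. The SD between replicates over genes on the log2 scale differed less, at 0.187, 0.187, 0.213 and 0.246 in the same order. The first principal component of log2 counts-per-million (CPM) values held 56.1% of the variance and separated the arms.

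The files hold a row for an NBD1 reporter in every library. Its footprints stood at 9105 ± 33.2 CPM in the shRNA control and 7136 ± 137 CPM with shNBD1 (mean ± SD, n = 2 each). The log2 fold change was -0.35 ± 0.07 (SE), with an adjusted p of 0.00527 in edgeR's quasi-likelihood test. Both shNBD1 libraries lay below both control libraries. The fold stayed between -0.37 and -0.33 under all 16 alternatives, but the call was lost without any single library of the comparison, where the adjusted p reached 0.0782. With the inhibitors the reporter stood at 7980 ± 329 CPM against 8146 ± 272 CPM in their control, a log2 fold change of -0.03 ± 0.07 (adjusted p = 0.855). The difference between the treatment effects on the reporter, -0.32 on the log2 scale, did not pass the threshold (adjusted p = 0.0614). It passed under 6 of 19 alternatives, so this result depended on the settings.

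**Figure D1:**
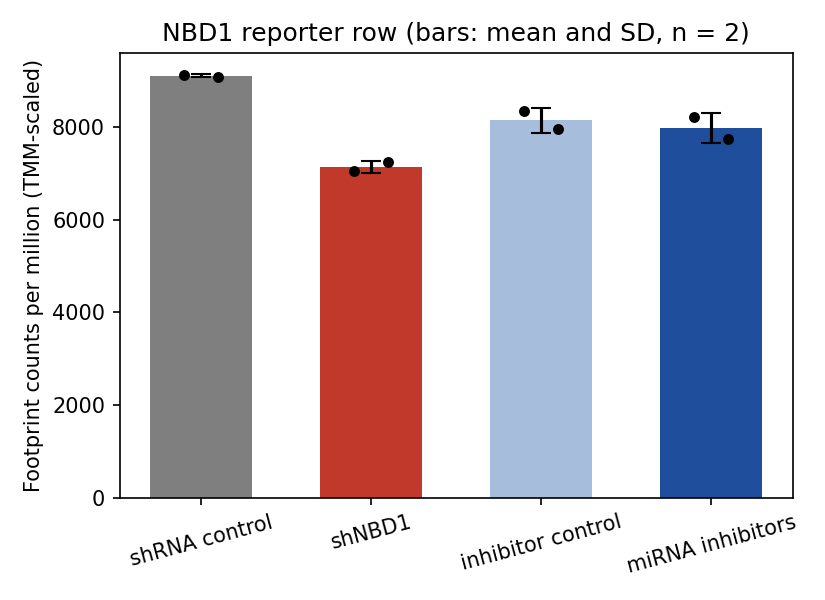
Footprint CPM on the NBD1 reporter row in the 4 groups. Bars give the mean and SD of 2 libraries and points the libraries: the shNBD1 libraries stood at 7040 and 7233 CPM, and the shRNA control libraries at 9129 and 9082 CPM.

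With shNBD1, the gene of smallest p among those that rose was COL12A1, a collagen of the extracellular matrix. It went from 63.3 ± 2.49 to 355.3 ± 8.51 CPM, a log2 fold change of 2.49 ± 0.18. MATN3, a cartilage matrix protein, rose by 2.01 ± 0.15, and SLIT3, a secreted guidance ligand, by 1.43 ± 0.11. RHOB, a small GTPase of actin regulation, rose by 1.65 ± 0.13, TMOD1, which caps actin filaments, by 1.14 ± 0.10, and KIF5C, a kinesin motor, by 1.12 ± 0.09. The small heat-shock protein HSPB8 rose by 1.88 ± 0.15, while ANXA1, which binds phospholipids, rose from 86.3 ± 1.16 to 205.6 ± 7.48 CPM. TFPI, an inhibitor of coagulation, rose by 1.05 ± 0.09, and PLAT, the tissue plasminogen activator, by 0.82 ± 0.07. SUN2, of the nuclear envelope, rose by 0.82 ± 0.07 and ANKRD52, a regulatory subunit of a phosphatase that acts on Argonaute proteins, by 0.81 ± 0.07. Adjusted p-values of these 12 genes, the 12 of smallest p that met the fixed rule, ran from 3.82e-05 to 7.45e-05 in edgeR's quasi-likelihood test.

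The gene of smallest p in the whole comparison fell. GFPT1, the rate-limiting enzyme of the hexosamine pathway (chromosome 2, 69319780 to 69387227, GRCh38), dropped from 184.0 ± 3.58 to 45.0 ± 3.42 CPM, a log2 fold change of -2.03 ± 0.08 (adjusted p = 9.31e-07, edgeR). PSAP, the precursor of the lysosomal saposins (chromosome 10, 71816298 to 71851251), fell by 1.21 ± 0.07. Other lysosomal or secretory genes among the 12 were ATP6V1E1, a subunit of the vacuolar proton pump, at -1.13 ± 0.07, and SCPEP1, a carboxypeptidase, at -1.37 ± 0.09. CAPZA1, which caps actin filaments, stood at -1.23 ± 0.07, PNP, of purine salvage, at -1.03 ± 0.06 and RBBP4, a histone chaperone, at -1.18 ± 0.08. ENPP4 fell by 1.77 ± 0.11, DENND6A by 1.90 ± 0.13, AMMECR1 by 1.92 ± 0.13, ZNF460 by 1.24 ± 0.08 and TMEM70 by 1.14 ± 0.08. In all, 1222 genes rose and 1218 fell of 13306 tested, 182 and 148 of them by at least 2-fold, and the median change of called genes was 1.40-fold. These 24 leading genes kept their call under all 16 alternatives. The counts did not: they were 266 higher and 266 lower without shRNA control replicate 1, 355 and 361 without replicate 2, 537 and 485 without shNBD1 replicate 1, and 325 and 294 without its replicate 2. On the 4 libraries of this comparison alone, whose replicates agree more closely than those of the other arm, 2725 rose and 2589 fell.

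**Figure D2:**
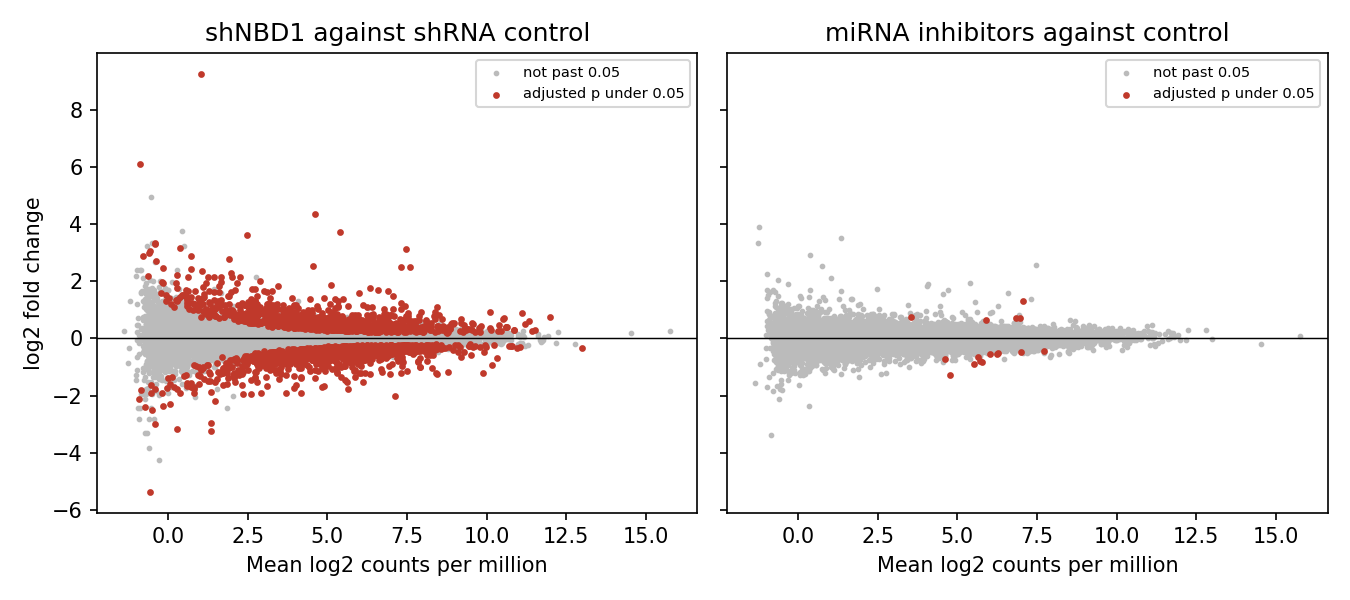
Log2 fold change against mean log2 CPM for each tested gene, with shNBD1 on the left and the miRNA inhibitors on the right. Red points have an adjusted p under 0.05 in edgeR's quasi-likelihood test: 2440 of 13306 genes on the left and 16 on the right.

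For scale, 18.3% of all genes tested were called with shNBD1. The shares of proteasome and mitotic genes called were only slightly above this, and that of ribosomal proteins was below it. Among the 21 gene lists fixed before the data were examined, p53 targets changed most with shNBD1. Of 20 measured, 12 fell and none rose (15 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.50. GDF15, a stress-induced cytokine, fell by 1.53 ± 0.20, SESN1, a regulator of growth signalling, by 1.20 ± 0.17, DDB2, of DNA repair, by 0.82 ± 0.17 and CCNG1, a cyclin, by 0.75 ± 0.14. The list passed camera with a preset correlation (adjusted p = 7.47e-06), but not with an estimated correlation (adjusted p = 0.71). In cholesterol synthesis 7 of 24 genes fell and 1 rose (9 and 1 adjusted over the list alone), led by MSMO1 at -1.47 ± 0.16 and INSIG1, a sterol sensor, at -1.20 ± 0.18, with IDI1 at -0.82 and STARD4 at -0.69 (camera adjusted p = 0.0057, and adjusted p = 0.735 with an estimated correlation). Among deadenylation and decapping factors 5 of 20 fell and none rose (the same counts adjusted over the list alone). CNOT11, of the deadenylase complex, fell by 1.12 ± 0.08 and DCP2, the decapping enzyme, by 0.98 ± 0.08, beside PATL1 at -0.43 and CNOT8 at -0.40 (camera adjusted p = 0.00606, and adjusted p = 0.71 with an estimated correlation).

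Mitochondrially encoded proteins fell in 5 of 13 cases and rose in none (6 fell adjusted over the list alone), with MT-ND2 at -0.71 ± 0.10, MT-ND3 at -0.60, MT-ND1 at -0.58 and MT-ATP6 at -0.48 (camera adjusted p = 0.00819, and adjusted p = 0.71 with an estimated correlation). Cytosolic ribosomal proteins rose in 8 of 74 cases and fell in none (4 rose adjusted over the list alone), among them RPS27A at 0.42 and RPL36 at 0.39 (camera adjusted p = 0.00242, and adjusted p = 0.855 with an estimated correlation). Proteasome subunits fell in 7 of 31 cases (8 adjusted over the list alone), such as PSMC6 at -0.38 and PSMD6 at -0.36 (camera adjusted p = 0.011, and adjusted p = 0.722 with an estimated correlation). Of 25 mitotic genes 5 fell and 1 rose (7 and 1 adjusted over the list alone). TOP2A, a topoisomerase, fell by 0.47 ± 0.07, while AURKB, a mitotic kinase, rose by 0.61 ± 0.08 (camera adjusted p = 0.00819, and adjusted p = 0.735 with an estimated correlation). Of 24 targets of ATF4 in the integrated stress response, 5 fell and 2 rose (8 and 2 adjusted over the list alone), with the cystine transporter SLC7A11 at -1.30 ± 0.15 and ATF3 at 1.01 ± 0.19. That list had a camera adjusted p of 0.0249, which became 0.0632 without shRNA control replicate 1 and 0.0621 on genes with a mean of at least 50 counts, and adjusted p = 0.735 with an estimated correlation.

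The remaining 13 lists did not pass camera with shNBD1. Of 24 let-7 targets 9 rose and 2 fell (9 and 4 adjusted over the list alone), against 18.3% of all genes called. Among them were NR6A1 at 1.29 ± 0.28, LIN28B at 1.08 ± 0.13, ARID3B at 0.89 ± 0.11 and CCND2 at -0.86 ± 0.09 (camera adjusted p = 0.162). Fry did pass this list (adjusted p = 0.00103, its smallest among the 21 lists), and of the 13 also nuclear oxidative phosphorylation (0.0138). The miR-17 family targets held 5 that rose and 3 that fell of 26, led by ANKFY1 at -0.98 ± 0.07 and ZBTB4 at 0.91 ± 0.15 (camera adjusted p = 0.507). The miR-15/16 targets held 3 and 2 of 18, led by CARD10 at 0.82 ± 0.19 (camera adjusted p = 0.946). Of 13 genes of RISC, the complex that carries small RNAs, and of miRNA processing, AGO1 rose by 0.40 ± 0.09 and TNRC6C by 0.40 ± 0.09 (camera adjusted p = 0.727). Camera adjusted p-values were 0.85 for HSF1 chaperones, where HSPB1 rose by 0.87, 0.235 for TRiC and prefoldin, where VBP1 fell by 0.58, 0.946 for the ER unfolded protein response, 0.162 for translation factors, where EEF1A2 rose by 0.67, and 0.344 for ribosome collision factors, where GIGYF1 rose by 0.58. They were 0.85 for interferon-stimulated genes, where ISG20 rose by 1.10 and BST2 fell by 0.85, 0.452 for replication-dependent histones and 0.109 for nuclear oxidative phosphorylation, where ATP5MC3 fell by 0.70. Of 8 measured markers of cell types other than 293T, 1 fell, the macrophage marker CD68 at -0.52 ± 0.12 (camera adjusted p = 0.541). Calls of single list members were less stable than those of the leading genes. Of the 103 genes called and named for this comparison, 58 lost their call without shRNA control replicate 1, 50 without its replicate 2, 43 without shNBD1 replicate 1 and 58 without its replicate 2. These included AGO1, TNRC6C, RPS27A, PSMC6, DDB2, CCNG1, IDI1 and STARD4, each lost in at least 2 of the 4 fits.

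**Figure D3:**
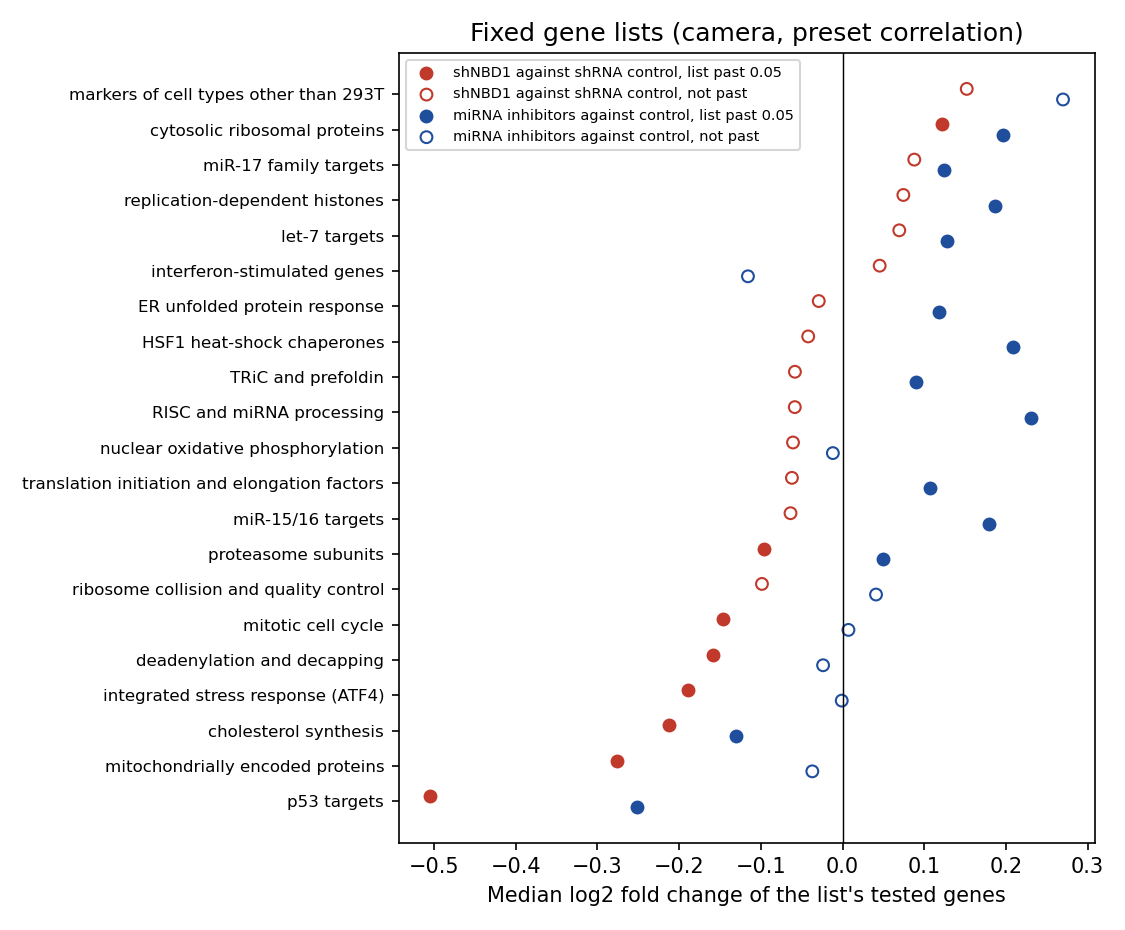
Median log2 fold change of the measured members of each of the 21 fixed lists, with shNBD1 in red and with the miRNA inhibitors in blue. Filled points passed camera at a preset correlation, 8 lists in red and 13 in blue; with an estimated correlation 0 lists passed in either comparison.

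With the miRNA inhibitors few single genes passed the threshold in the main fit, though with the replicate number as a block 355 rose and 320 fell. Values here are from the main fit unless stated. TNRC6A, the scaffold that joins Argonaute to the deadenylases, rose from 57.2 ± 5.54 to 89.1 ± 3.15 CPM, a log2 fold change of 0.64 ± 0.08 (adjusted p = 0.028, edgeR). It did not pass without inhibitor control replicate 1 (adjusted p = 0.0866) or without inhibitor replicate 2 (adjusted p = 0.0799). ANKRD52 rose by 0.71 ± 0.06 (adjusted p = 0.00493), SNRPA, a spliceosomal protein, by 0.72 ± 0.08, THBS1, a matrix glycoprotein, by 1.30 ± 0.18 and YOD1, a deubiquitinase, by 0.75 ± 0.12. Of the 11 that fell, MSI2, an RNA-binding protein, dropped by 0.88 ± 0.10, NOTCH3, a receptor, by 0.79 ± 0.10, ITGA8, an integrin, by 1.28 ± 0.19 and STMN3, of microtubule dynamics, by 0.82 ± 0.12. The other 7 were GRIPAP1 at -0.64, RTL8A at -0.50, MAPK3 at -0.54, REEP2 at -0.72, CSNK1E at -0.43, MAPK8IP2 at -0.54 and CIRBP at -0.47. Values not past the threshold included AGO2 at 0.69 ± 0.13, DICER1 at 0.44 ± 0.08, OTUD4 at 0.61 ± 0.10, MGST1 at 0.76 ± 0.14 and NUP160 at 0.35 ± 0.06 (adjusted p from 0.0682 to 0.0803). AGO2 and DICER1 passed with DESeq2 (adjusted p = 0.00101 and 0.00962). In edgeR they passed with no filter on low counts (0.0103 and 0.022) and with the replicate block (0.00654 and 0.00972). On the 4 libraries of the comparison alone edgeR gave 0.568 for each. In all, 5 genes rose and 11 fell, while 2183 had an unadjusted p under 0.05. All 16 calls rest on a spread pooled with the tighter shRNA arm: on the 4 libraries of this comparison alone the same test called 0 and DESeq2 on all libraries called 42 higher and 75 lower. Without inhibitor control replicate 1, 2 rose and 2 fell, and without inhibitor replicate 2, 3 and 3; without inhibitor control replicate 2 the counts were 352 and 287, and without inhibitor replicate 1, 494 and 436.

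As a group, the 13 genes of RISC and miRNA processing were higher with the inhibitors, with a median log2 fold change of 0.23 (camera adjusted p = 9.26e-05, and adjusted p = 0.163 with an estimated correlation). The median was 0.14 without inhibitor control replicate 2, 0.137 without inhibitor replicate 1 and 0.27 without inhibitor control replicate 1, and the list passed in these fits. Of them 1 rose over all genes tested and 6 adjusted over the list alone. Fry, which passed 7 of the 21 lists, gave this list an adjusted p of 0.000394. The let-7 targets had a median of 0.13 (camera adjusted p = 0.00125), the miR-15/16 targets 0.18 (0.00324) and the miR-17 family targets 0.12 (0.0182), each with adjusted p = 0.163 with an estimated correlation. Fry adjusted p-values of these target lists, in the same order, were 0.000177, 0.00645 and 0.00874. None of their members passed over all genes tested, while 8, 0 and 3 rose adjusted over the list alone. The smallest p-values among them belonged to DICER1, itself a let-7 target, CDC25A at 0.53 ± 0.10 and FYCO1 at 0.50 ± 0.10. The miR-17 list did not pass without inhibitor control replicate 2 (median 0.10, adjusted p = 0.104) or without inhibitor replicate 1 (median 0.06, adjusted p = 0.126). HSF1 chaperones had a median of 0.21, with 7 of 23 that rose adjusted over the list alone and 0 over all genes (camera adjusted p = 6.02e-08), and ER unfolded protein response genes a median of 0.12, with 1 of 22 and 0 (0.0185), both with adjusted p = 0.163 with an estimated correlation. The median of the HSF1 list was 0.13 without inhibitor replicate 2 and 0.11 without both that library and inhibitor control replicate 1, and the list passed in both fits. The ER list did not pass without inhibitor replicate 1 (median 0.14, adjusted p = 0.144), and it passed with medians of 0.06 without inhibitor control replicate 1, 0.06 without inhibitor replicate 2 and 0.07 without both.

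Cytosolic ribosomal proteins had a median of 0.20 with the inhibitors, with 9 of 74 that rose adjusted over the list alone and 0 over all genes (camera adjusted p = 8.76e-16, and adjusted p = 0.404 with an estimated correlation). Translation factors had a median of 0.11 (camera adjusted p = 2.31e-05, and adjusted p = 0.404 with an estimated correlation), and histones 0.19 (1.52e-07, and adjusted p = 0.31 with an estimated correlation). The p53 targets had a median of -0.25, with 4 of 20 that fell adjusted over the list alone and 0 over all genes (4.51e-05, and adjusted p = 0.31 with an estimated correlation). Cholesterol synthesis had a median of -0.13 (0.00554, and adjusted p = 0.596 with an estimated correlation). Fry passed none of these lists, with adjusted p from 0.128 for histones to 0.493 for cholesterol synthesis. Inhibitor control replicate 1 and inhibitor replicate 2 lay farthest apart on the third principal component (20.4 and -23.5). A fit without both sets control replicate 2 against inhibitor replicate 1. A shift shared by libraries of the same number cannot be told apart from the treatment there. With the replicate number as a block the medians stayed at 0.20 for ribosomal proteins, 0.11 for translation factors, -0.26 for p53 targets and -0.13 for cholesterol synthesis. Without both libraries the median was 0.06 for histones, which still passed (adjusted p = 0.000435), -0.02 for ribosomal proteins, 0.02 for translation factors, -0.03 for p53 targets and 0.07 for cholesterol synthesis, whose direction turned (adjusted p = 0.0011). TRiC and prefoldin (0.0194, and adjusted p = 0.404 with an estimated correlation) and proteasome subunits (0.0364, and adjusted p = 0.452 with an estimated correlation) also lost their call without those libraries, with adjusted p of 0.676 and 0.377. The other lists did not pass camera: adjusted p was 0.948 for deadenylation and decapping, 0.948 for ATF4 targets, 0.424 for ribosome collision, 0.301 for interferon-stimulated genes, 0.621 for mitotic genes, 0.263 for mitochondrially encoded proteins, 0.0858 for nuclear oxidative phosphorylation and 0.948 for markers of other cell types. Without both libraries the ATF4 targets had a median of -0.13 (adjusted p = 0.00222) and the markers of other cell types -0.34 (adjusted p = 0.013), so these lists passed there.

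Whether the treatments acted differently was tested on the difference of their effects, the change with shNBD1 minus that with the inhibitors. It passed for 463 genes with a positive difference and 527 with a negative one. GFPT1 differed by -2.40 ± 0.11 (adjusted p = 4.1e-06, edgeR), and AMMECR1, ENPP4, TMEM70, CAPZA1 and PNP by -2.15, -1.95, -1.39, -1.35 and -1.10. On the positive side OLFML2A, a matrix protein, differed by 1.79 ± 0.20, TMOD1 by 1.66 ± 0.14, SLIT3 by 1.63 ± 0.17, KIF5C by 1.22 ± 0.12, PLAT by 1.03 ± 0.10 and GJA1, a gap junction protein, by 0.96 ± 0.11. Among lists, 9 passed camera, all lower with shNBD1 than with the inhibitors, and none with an estimated correlation (smallest adjusted p = 0.532). The counts were 82 and 105 without shRNA control replicate 1, 96 and 118 without replicate 2, 155 and 180 without shNBD1 replicate 1, and 90 and 109 without its replicate 2. Across the 13306 genes, which are not independent replicates, the log2 fold changes of the treatments had a Pearson r of 0.152 and a Spearman rho of 0.133. The Pearson value was 0.0159 without inhibitor control replicate 1 and 0.0215 without inhibitor replicate 2. It was 0.239 without inhibitor control replicate 2, so it depended on which library was left out. Of the 16 genes called with the inhibitors, 7 were also called with shNBD1, where 18.3% of all genes tested were called. Of these 7 genes, 4 moved in the same direction.

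Between the control groups, which received different reagents, 1800 genes were higher in the shRNA control and 1811 lower. PNP was at 556.8 ± 1.33 CPM in the shRNA control and 199.98 ± 2.95 CPM in the inhibitor control, a log2 difference of 1.48 ± 0.06, and PCDH19, a protocadherin, differed by 1.79 ± 0.08. TRIM43 differed by 4.87 ± 0.31, TRIM49B by 5.39 ± 0.32 and TRIM49D1 by 5.24 ± 0.27. TRIM49C stood at 7.29 ± 0.45 CPM against 0.03 ± 0.04 CPM. The TRIM49 genes are near-identical copies, so their reads may be shared. Lower in the shRNA control were MGST1, a glutathione transferase, at -4.64 ± 0.28, UNC13D at -4.25 ± 0.26, CRABP2, a retinoic acid carrier, at -2.70 ± 0.12, COL5A1, a collagen, at -1.79 ± 0.10 and the ribosomal protein RPL41 at -1.45 ± 0.07. MTRNR2L8, a nuclear copy of mitochondrial rRNA sequence whose reads may be shared, stood at -1.29 ± 0.08. Of 24 ATF4 targets 17 were higher and 1 lower, with a median of 0.42 (19 and 1 adjusted over the list alone), of 25 mitotic genes 14 were higher and none lower, with a median of 0.32 (17 adjusted over the list alone), and of 13 mitochondrially encoded proteins 12 were lower, with a median of -0.80 (13 adjusted over the list alone). Camera adjusted p-values were 1.13e-07, 1.13e-07 and 9.49e-10, and adjusted p = 0.431 for each with an estimated correlation. Of the markers of other cell types, CD68 was higher in the shRNA control by 1.51 and the smooth-muscle actin ACTA2 lower by 0.76 on the log2 scale. The counts fell to 509 and 568 without shRNA control replicate 1 and to 608 and 659 without its replicate 2. Reagent, culture and library batch cannot be told apart in this comparison. PNP, ATF4 targets and mitotic genes, higher in the shRNA control, fell with shNBD1: PNP to 272.4 CPM and the lists with medians of -0.19 and -0.15. Mitochondrially encoded proteins, lower in the shRNA control, also fell with shNBD1 (median -0.28). As shNBD1 was compared with this control only, a shift of the control and an effect of shNBD1 cannot be told apart for them.

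**Figure D4:**
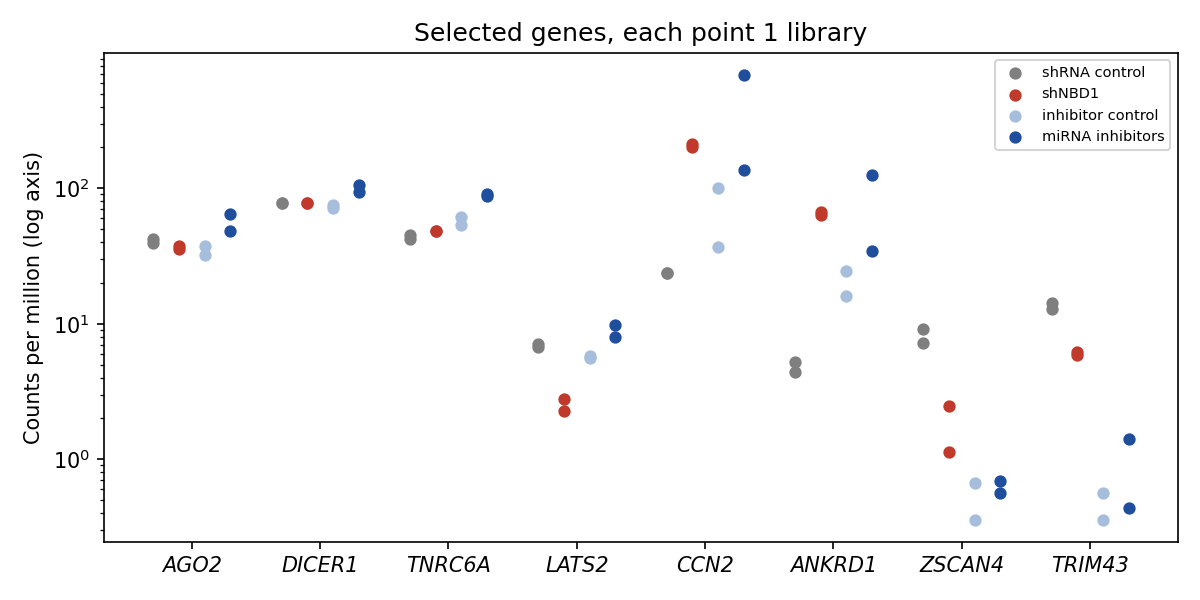
Footprint CPM of 8 genes in each of the 8 libraries, on a log axis. AGO2, DICER1 and TNRC6A belong to the silencing machinery, LATS2, CCN2 and ANKRD1 to the YAP pathway, and ZSCAN4 and TRIM43 to the targets of DUX4.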

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

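Choices named here were planned before the data were examined, except the quality weights and the fit without both libraries. With an estimated correlation 0 lists passed for shNBD1 and 0 for the inhibitors, in place of 8 and 13. For the inhibitors the counts of genes higher and lower, 5 and 11, became 74 and 105 with no filter on low counts, 37 and 58 at an adjusted p of 0.10, 42 and 75 with DESeq2, and 0 and 0 on their 4 libraries alone, where the spread comes only from the more variable arm. With quality weights 2 genes fell. Without inhibitor control replicate 1 and inhibitor replicate 2 together, 229 rose and 272 fell, with each lone library assumed to vary like the other groups; the list of ribosomal proteins then had a median of -0.01794, translation factors 0.02078 and cholesterol synthesis 0.06612, all turned in camera's direction; the cause was not tested further. For shNBD1 the counts of 1222 and 1218 became 2725 and 2589 on its 4 libraries alone and 2384 and 2426 with quality weights. For the difference of effects they became 863 and 948 at an adjusted p of 0.10. Between the controls DESeq2 called 1093 lower. Leaving out each library in turn gave ranges of 266 to 537 higher and 266 to 485 lower for shNBD1, 2 to 494 and 2 to 436 for the inhibitors, 82 to 585 and 105 to 550 for the difference, 509 to 1595 and 568 to 1663 for the controls, and 0.01585 to 0.2392 for the correlation of effects. Fewer libraries leave less to estimate the spread from, and where an arm keeps 1 library it is assumed to vary like the others. The number of lists passing ranged from 7 to 8 for shNBD1 and 9 to 13 for the inhibitors, and cholesterol synthesis with the inhibitors had a median from -0.3042 to -0.005136, with the direction of camera turned in the latter, without inhibitor replicate 2. Replicate numbers were not used as a pairing in the main fit: deviations of same-numbered libraries correlated at 0.015 in the shRNA arm and 0.42 in the inhibitor arm, with only 2 pairs each. In the inhibitor arm both groups fell from replicate 1 to 2 on the third component, from 20.4 to 4.26 in the control and from 2.26 to -23.5 with the inhibitors. A shift shared by replicate number thus stays open in that arm. The block was 1 term for both arms, and none was fitted for the inhibitor arm alone. With the replicate block 355 rose and 320 fell with the inhibitors, 897 and 971 differed between effects, and the 2440 calls of shNBD1 were all among 3408. Of the values of named genes called for shNBD1, 217 of 1644 lost the call, and for the inhibitors 55 of 270, and none turned direction in any comparison. Of the values of named genes not called in the main fit, 147 of 758 came to be called for the inhibitors. For the difference 6 of 19 did, and for the controls 3 of 16. The seed-site tests, with their alternatives, were not run.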

Other observations

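The DUX4, YAP and TAZ, SRF and immediate early lists and the tests that weigh the patterns were chosen after the values were seen. So was the fit without 2 inhibitor-arm libraries, whose reading was set before it was run. The p-values of the 4 added lists come from the values that led to these lists, so they are descriptive only. The added lists were not refitted with a library left out or with the replicate block. Genes that the embryonic transcription factor DUX4 is known to switch on were higher in the shRNA arm. Of 36 members with reads 29 passed the filter on counts, and members low in the inhibitor arm could pass it only through the shRNA arm. Of these 29, 25 were higher in the shRNA control than in the inhibitor control and none lower, with a median log2 difference of 3.995, or 3.92 with the 2 members at 0 in the inhibitor control set to a floor of 3 counts over the group (camera p = 2.73e-16, and p = 0.0318 with an estimated correlation, adjusted p = 0.127 over the 4 added lists). Together, 28 of them took 98.3 and 91.9 CPM in the shRNA control, 46.6 and 48.0 CPM with shNBD1, 9.92 and 13.02 CPM in the inhibitor control and 11.1 and 22.5 CPM with the inhibitors. ZSCAN4, a gene of the early embryo, had 137 and 88 counts in the shRNA control, 16 and 36 with shNBD1, 7 and 13 in the inhibitor control and 11 and 6 with the inhibitors. DUX4 itself, with 8 and 8 counts in the shRNA control, 5 and 8 with shNBD1, 7 and 11 in the inhibitor control and 4 and 4 with the inhibitors, was too low to be tested, so a higher level of DUX4 in the shRNA control was not shown. Within the shRNA arm 8 of the 29 fell with shNBD1 and none rose, ZSCAN4 by 2.18 on the log2 scale (adjusted p = 0.00114, edgeR); the list had a camera p of 4.09e-06, and p = 0.143 with an estimated correlation. With the inhibitors 23 of the 29 were positive and 0 were called, with a median of 0.92 (limma's camera adjusted p = 0.00171, and adjusted p = 0.363 with an estimated correlation). The difference between the treatment effects had a median of -1.87 (limma's camera adjusted p = 2.43e-06, and adjusted p = 0.361 with an estimated correlation). Both medians draw on few counts in the inhibitor arm, such as TRIM49 at 1 and 3 in the control and 3 and 6 with the inhibitors. Of the inhibitor libraries only replicate 2 had a summed CPM above both controls.

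Reads of 1 transcript spread over near-identical copies are argued against as the whole source of the DUX4 pattern, since 5 of the 6 members outside the copied families were also higher in the shRNA control. A single deviating library is argued against too: 23 of 29 members had all 4 shRNA-arm libraries above all 4 inhibitor-arm libraries. Of all genes 14.4% did, and 1.43% would by chance. The list was written after the values were seen, and the filter favours members high in the shRNA arm. Neither 23 of 29 nor 5 of 6 can therefore be tested against those shares. A difference between the arms other than the reagent, such as cell stock, culture or batch, cannot be told apart from the reagent, because each arm is a block of its own and 3586 genes outside the list also differed between the controls.

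Targets of YAP and TAZ, coactivators that respond to cell shape and density, and of SRF, which responds to actin, were higher with shNBD1. The lists of this paragraph were written after these values were seen, so their p-values are descriptive only. Of 21 YAP and TAZ targets 10 rose and 1 fell, with a median of 0.62 (camera p = 8.7e-06, and p = 0.0876 with an estimated correlation), and of 16 SRF and actin targets 12 rose and none fell, with a median of 0.71 (1.66e-10, and p = 0.108 with an estimated correlation). CCN2 went from 23.6 and 23.5 CPM to 202.0 and 213.4 CPM, and ANKRD1 from 5.25 and 4.42 CPM to 66.2 and 64.0 CPM. The member that fell was LATS2, a kinase that restrains YAP, from 6.71 and 7.12 CPM to 2.28 and 2.79 CPM. In the inhibitor arm LATS2 stood at 5.62 and 5.82 CPM in the control and 7.94 and 9.74 CPM with the inhibitors, so the higher targets there did not go with a lower LATS2. With the inhibitors the YAP and TAZ list moved likewise: 19 of 21 members were positive, with a median of 0.51 and 7 that rose adjusted over the list alone, though 0 passed over all genes (limma's camera p = 1.32e-06, and p = 0.0708 with an estimated correlation). The inhibitor libraries differed on this list, with replicate 2 higher by a median of 0.29 in log2. CCN1 stood at 70.8 and 231.4 CPM in them and ANKRD1 at 34.7 and 125.6 CPM. The difference between the treatment effects on this list did not pass (limma's camera adjusted p = 0.0882), so these values do not set the treatments apart on it. The SRF and actin targets had a median of 0.27 with the inhibitors, with 0 called over all genes (limma's camera adjusted p = 0.00746, and adjusted p = 0.437 with an estimated correlation). Their difference between treatments had a median of 0.49, with 15 of 16 positive and 4 called (limma's camera adjusted p = 2.21e-06, and adjusted p = 0.361 with an estimated correlation). Immediate early genes did not pass with shNBD1 (limma's camera adjusted p = 0.391). With the inhibitors all 19 were positive, with a median of 0.55 and 7 that rose adjusted over the list alone (limma's camera adjusted p = 1.26e-06, and adjusted p = 0.363 with an estimated correlation).

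Variation between culture dishes unrelated to the treatment stays open for this pattern. In the inhibitor arm, where the labels give no hairpin, CCN2 stood at 37.1 and 100.0 CPM in the control and at 135.8 and 682.3 CPM with the inhibitors. The ratio of the list's median difference between replicates to its median effect was 0.167 in the shRNA control, 0.211 with shNBD1 and 0.331 in the inhibitor control, and reached 0.470 in the inhibitor group, with a 95% bootstrap interval over members of 0.249 to 1.295. That interval was added after the ratio had been seen to lie just under the bound of 0.5 first set, which alone would have read as evidence against dishes. Replicates that share a dish would also hide such variation.

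The lists of let-7, miR-17 and miR-15/16 targets and of RISC genes, higher with the inhibitors, are what relief of miRNA silencing might produce, a hypothesis only, since the labels do not name the miRNAs that the inhibitors target. The seed-site tests that bear on it were not run. On the difference between the treatment effects none of these lists passed camera (adjusted p from 0.0788 for RISC to 0.955 for let-7 targets). Camera thus does not set the treatments apart on them. Fry, which does not compare a list with other genes, passed there for RISC (adjusted p = 0.0116) and miR-15/16 targets (0.0326). It did not pass for let-7 (0.0532) or miR-17 targets (0.0616). Of 13 RISC genes 3 were called lower with shNBD1 than with the inhibitors and 0 higher, against 7.44% of all genes called in either direction. Whether the deviation of inhibitor replicate 2 and control replicate 1 from their partners is the whole source of the higher lists stays open. Without both libraries 4 of the 4 lists passed camera at the preset correlation. The RISC median was 0.31 in that fit, against 0.14 without control replicate 2 alone. Passing cannot decide the question, because each library of a pair deviates from its partner by the same amount. The libraries kept also differ in replicate number. That fit has 1 library in each inhibitor-arm group, and ATF4 targets and markers of other cell types came to pass in it as well, so passing there is not particular to these lists. A single deviating library stays open for the lists as a set, since 3 of the 4 passed in all fits that left out 1 library and the miR-17 list did not. With the estimated correlation, which was negative for all 4 lists (-0.06 to -0.02), none passed, but that form of camera rests on 4 residual degrees of freedom, so the lost calls do not speak for members that vary together.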
